A study of Homo sapiens with 19 samples.

How the data were processed

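Gene expression was measured by RNA sequencing in 19 libraries of the neuroblastoma line SHEP TET21N, in 10 groups defined by MYCN state and time point. Per the labels' protocols, MYCN-low cells were grown with doxycycline and MYCN-high cells without it, and doxorubicin at 0.1 µg/ml was given for 72 h and then washed out. The labels' protocols describe ERCC spike-in mix added to each sample before processing, ribosomal RNA removed with the RiboGold kit and libraries made with the ScriptSeq kit, while the molecule field of the labels says polyA RNA. STAR 2.4.0h1, HTSeq and the genome build hg19 are named in the submitters' processing notes, with no annotation, strand setting or filter. The deposited table holds read counts per gene symbol for every library, and its values were whole numbers with a different sum for each library. It has 23459 lines, 23367 for genes and 92 for ERCC RNAs, and no column outside the 19 libraries. Symbols were used as the table gives them, and no coordinates were used. Reads that fit several near-identical genes, such as histones, can be split or lost in such counts, so single members are uncertain.

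Counts were analysed in R 4.3.3 with edgeR 4.0.16. ERCC counts were set aside, genes were kept by filterByExpr on the groups (14793 genes), libraries were scaled by TMM, and a quasi-likelihood fit with 1 coefficient per group was tested in 19 contrasts. Each contrast was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. With 19 libraries in 10 groups the fit had 9 residual degrees of freedom, and the biological coefficient of variation was 0.204. The MYCN-low group at 14 days has 1 library, which is assumed to vary like the other groups. The contrasts were MYCN-high against MYCN-low cells at each time, each treated time against untreated cells of the same state, 14 days against 72 h in each state, and the difference between the responses of the states at each treated time. Total counts ran from 16547663 to 27664604 per library, and the floor used for groups at 0 was 3 counts over the group, which covers counting error only. The groups of 2 are too small for a test of single outlying libraries or for regrouping the samples.

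The gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names 24 tested marker genes in every contrast, then genes past the threshold with an absolute log2 fold change of at least 1 and a mean of at least 5 CPM, in which every library of 1 group lay above every library of the other, by size of change (up to 6, 4 or 3 per direction, depending on the contrast), and up to 4 members of each called list by smallest p. Some genes of the last kinds were left out for length. Of the marker genes 21 are given, and other results on some genes and 1 gene list are not reported here. In the differences between responses, which involve 4 groups, the separation of libraries was not required. Of 33 gene lists 32 had enough tested members, and mitochondrially encoded messenger RNAs had fewer than 3. The list of structured and mitochondrial ribosomal RNAs is called the RNA-quality list, but RNA quality itself was not measured. Per the protocols ribosomal RNA was removed, and the list cannot tell that step apart from RNA quality. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a contrast, and repeated with an estimated correlation. Of the called lists in the text, 11 had members at 0 counts in a group, and setting these to their bound moved a list's median, printed or not, by at most 0.46.

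Alternatives were size factors of DESeq2 1.42.0 in the edgeR fit, the Wald test of DESeq2, no filter on low counts, the replicate letter as a block, ERCC scaling, and leaving out each library in turn. ERCC scaling used the summed counts of all 92 ERCC RNAs, of which 33 had a mean of at least 10 counts. GC content and length were taken from GENCODE release 29 for 14089 tested genes (95.2%). Principal components were computed on log2 CPM with a prior count of 2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

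The procedure was tested on simulated counts with 100 genes changed at each fold and no other difference between the groups. For 72 h in MYCN-high cells, on 14213 genes, 52% of 2-fold and 90% of 4-fold changes were recovered, with 9 false calls among 151. For 14 days in MYCN-low cells, on 14224 genes, these were 21% and 77%, with 5 false calls among 103. For the difference between responses at 72 h, on 14244 genes, they were 10% and 68%, with 3 false calls among 81. With no gene changed, 0 of 14230 genes were called.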

Results

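RNA sequencing read counts were measured in SHEP TET21N cells, an established human neuroblastoma line in which doxycycline switches off a MYCN transgene. MYCN is a transcription factor of the MYC family whose gene is amplified in part of neuroblastomas. Cells grown without doxycycline are called MYCN-high here, and cells grown with it MYCN-low. In each state, libraries were made from untreated cells, from cells after 72 h in 0.1 µg/ml doxorubicin, and from cells 3, 8 and 14 days after the drug had been removed. Doxorubicin is an anthracycline that traps topoisomerase II on DNA and causes DNA breaks. The 10 groups held 19 libraries, labelled biological duplicates with the letters B and C, and the MYCN-low group at 14 days held replicate B alone. Doxycycline was present in every MYCN-low culture and in no MYCN-high culture, so any effect of the antibiotic itself is part of every comparison of the states. Each state had a single untreated group, with no untreated cells matched to the later times. Any effect of time in culture is therefore part of every comparison with untreated cells and cannot be told apart from that of the drug. Total counts per library ran from 16547663 to 27664604. Of 23367 genes in the table, 14793 passed the filter on low counts and were tested. Genes carry the symbols of the table, which include older ones such as IL8 (CXCL8). Levels are mean CPM (counts relative to the scaled total count of a library) over the libraries of a group, n = 2 in each group and n = 1 in MYCN-low cells at 14 days. A value after ± approximates the standard error of a log2 fold change. It is the absolute log2 fold change divided by the square root of the F statistic of edgeR's test, not a separate estimate. In every gene named for the size of its change between 2 groups, all libraries of 1 group lay above all libraries of the other. This was not required in the differences between responses.

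At each time point the MYCN-high libraries lay lower on principal component 1 than the MYCN-low libraries. Across time points the states overlapped there, with MYCN-high cells at 72 h at 14.3 and -12.9, near untreated MYCN-low cells. Principal component 1 carried 47.6% of the variance of log2 CPM and component 2 carried 16.5%. MYCN-high libraries at 14 days lay at -85.4 and -86.1 on component 1, beside the untreated MYCN-high libraries at -77.2 and -90.6. Replicate C of MYCN-high cells at 8 days lay there too, at -81.2. On component 2 replicates B and C at 14 days lay at -27.3 and -9.8, against -35.3 and -29 untreated and 23.9 and 18.9 at 8 days. The MYCN-low library at 14 days lay at 68.5 on component 1, away from the untreated MYCN-low libraries at 6.5 and -15. Those untreated MYCN-low libraries were the least alike pair, with 2647 genes over 2-fold apart against 1103 to 1664 in the other groups of 2.

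**Figure D1:**
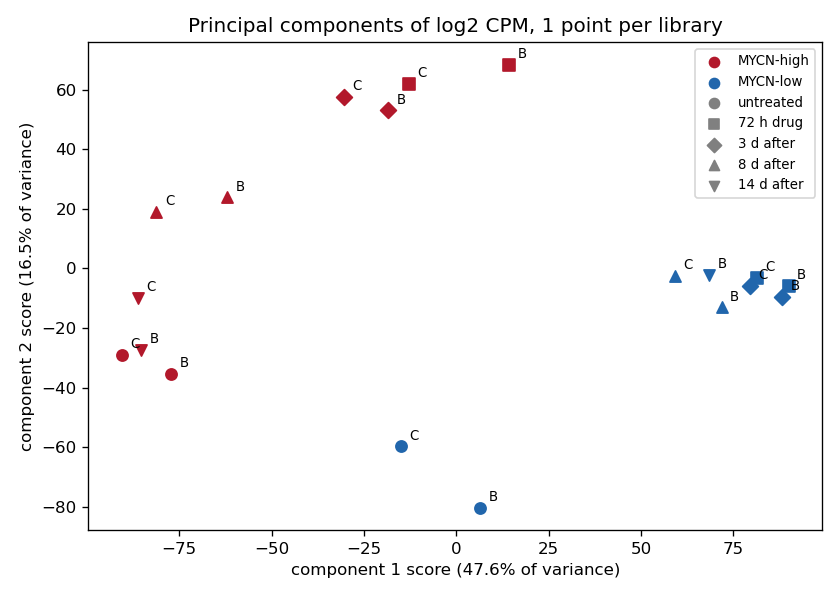
Principal components 1 and 2 of log2 CPM over the 14793 tested genes, 1 point per library, coloured by MYCN state and shaped by time point, with the replicate letter beside each point. MYCN-high libraries at 14 days (-85.4 and -86.1 on component 1) lie beside untreated ones, and the MYCN-low library at 14 days (68.5) does not.

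Before treatment, the MYCN transgene stood at 683 CPM in MYCN-high cells and 24.9 CPM in MYCN-low cells, a log2 difference of 4.78 ± 0.34, which matches the labels. MYC, its paralog, was lower in MYCN-high cells (-5.07 ± 0.49; 0.431 against 14.6 CPM). Genes for building ribosomes were higher in MYCN-high cells, among them POLR1B, a subunit of RNA polymerase I (2.15 ± 0.20), the nucleolar helicase gene DDX21 (1.83 ± 0.19) and the nucleolar protein gene NOP56 (1.77 ± 0.17). ODC1, the rate-limiting enzyme of polyamine synthesis and a MYC target, was higher by 1.54 ± 0.19 and nucleolin (NCL) by 1.71 ± 0.25. Genes of the extracellular matrix were lower in MYCN-high cells, among them COL6A1 (-3.42 ± 0.24) and COL6A2 (-3.77 ± 0.32).

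By list, 42 of 46 MYC targets were higher in MYCN-high cells and none lower (44 adjusted over the list alone), as were 38 of 40 genes of ribosome biogenesis and RNA polymerase I (38 adjusted over the list alone). camera gave adjusted p = 6.57e-31 and 4.19e-30 for these lists, and adjusted p = 0.0135 and 0.0522 with an estimated correlation. Of 25 genes of nucleotide and one-carbon synthesis, 17 were higher (22 adjusted over the list alone), with the purine synthesis genes PAICS (1.47 ± 0.18) and GART (1.45 ± 0.15) as examples. Among 57 mitochondrial ribosomal proteins 39 were higher (39 adjusted over the list alone). camera gave 6.63e-10 and 1.4e-13 for these, with adjusted p = 0.0927 and 0.109 with an estimated correlation. Of 32 matrix and mesenchymal genes 27 were lower (27 adjusted over the list alone), and of 18 YAP and TGF-beta targets 12 (12 adjusted over the list alone), including LTBP2, a matrix protein (-3.84 ± 0.33). camera gave 6.23e-16 and 1.12e-07, with adjusted p = 0.0676 and 0.123 with an estimated correlation. Of 38 secretory senescence factors 21 were lower and 1 higher (21 and 1 adjusted over the list alone), with the activin subunit INHBA (-4.98 ± 0.74) and TIMP1 (-2.34 ± 0.35) among them, and camera's adjusted p of 5.63e-06 became adjusted p = 0.197 with an estimated correlation. Without replicate B of the MYCN-low cells and replicate C of the MYCN-high cells in turn, 10 and 8 secretory senescence factors were lower, and 11 and 11 genes of nucleotide and one-carbon synthesis higher. The cell cycle inhibitor CDKN1A was lower by -2.10 ± 0.35. Single genes with large differences included HK2, a hexokinase (3.37 ± 0.34), the transcription factor TFAP4 (3.13 ± 0.30), and the amino acid transporters SLC7A2 (3.71 ± 0.28) and SLC6A15 (3.17 ± 0.31).

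In all, edgeR called 5189 genes in untreated cells, 2444 higher and 2745 lower in MYCN-high cells. Among 21 genes followed in every comparison, 10 passed. Besides those above, IL8 (-3.47 ± 0.68) and the thioredoxin inhibitor TXNIP (-1.88 ± 0.29) were lower. ABCB1, CCNB1 and FAS passed but lost the call in at least 1 edgeR fit without a library, with adjusted p up to 0.342 (FAS, without replicate C of the untreated MYCN-low cells). BAX, BBC3, CCND1, CCNE2, E2F1, GDF15, IL6, LMNB1, MDM2, MKI67 and TOP2A did not pass. Leaving out each library in turn gave 2903 genes without replicate C of the MYCN-high cells, 3102 without replicate B of the MYCN-low cells, and at most 6434, without replicate C of the MYCN-low cells.

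After 72 h of doxorubicin, MYCN-high cells raised CDKN1A and GDF15 and lowered genes of the cell cycle. CDKN1A, which blocks cyclin-dependent kinases, rose from 23.2 to 1120 CPM (log2 fold change 5.59 ± 0.40), and the stress cytokine GDF15 from 2.83 to 330 CPM (6.86 ± 0.75). MDM2, a ubiquitin ligase, rose by 2.35 ± 0.30, and BBC3, which promotes apoptosis, by 3.32 ± 0.35. The proliferation marker MKI67 fell from 687 to 44.6 CPM (-3.95 ± 0.52), the drug's target TOP2A from 1350 to 111 CPM (-3.61 ± 0.50) and the mitotic cyclin CCNB1 from 799 to 58.4 CPM (-3.78 ± 0.30). BTG2, an inhibitor of proliferation (4.35 ± 0.36), the mitochondrial reductase gene FDXR (3.90 ± 0.28) and the DNA damage sensor XPC (2.00 ± 0.17) rose as well. All 44 genes of G2 and mitosis fell (44 adjusted over the list alone), with a median of -3.94, and all 47 of DNA replication (47 adjusted over the list alone), with a median of -3.07. Of 25 genes of homologous recombination and the Fanconi pathway 23 fell (23 adjusted over the list alone), including BRCA1 (-3.26 ± 0.29). Of 42 replication-dependent histone genes 41 fell (42 adjusted over the list alone), and near-identical copies make single histone genes uncertain. Of 32 genes of lysosome and autophagy 26 rose (26 adjusted over the list alone), among them the protease gene CTSD (2.68 ± 0.26) and PSAP, a precursor of lysosomal activators (2.11 ± 0.18). camera's adjusted p for these 5 lists was 6.23e-47, 8.72e-48, 1.66e-25, 3.96e-41 and 4.74e-16, with adjusted p = 0.0457 for each with an estimated correlation.

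NF-kappaB targets and secretory senescence factors also rose in MYCN-high cells at 72 h. Of 21 NF-kappaB targets 13 rose (14 adjusted over the list alone), including the adhesion molecule VCAM1 (4.48 ± 0.51), the chemokine IL8 (4.00 ± 0.68) and the feedback inhibitor TNFAIP3 (3.29 ± 0.43). Of 38 secretory senescence factors 18 rose and 1 fell (19 and 1 adjusted over the list alone), with the cytokine LIF (2.64 ± 0.43) and TIMP1 (2.34 ± 0.35) as examples. Of 46 MYC targets 30 fell (32 adjusted over the list alone), ODC1 by -1.10 ± 0.19. camera gave 0.000118, 0.000382 and 4.95e-07 for these lists, and adjusted p = 0.177, 0.329 and 0.149 with an estimated correlation. Cytosolic ribosomal proteins went up in 45 of 74 members (48 adjusted over the list alone), RPS19 by 1.10 ± 0.20 and RPL12 by 0.99 ± 0.20, at camera's adjusted p of 1.01e-07 and adjusted p = 0.561 with an estimated correlation. In edgeR fits without a library 21 and 21 of them rose without replicates B and C of the untreated cells and 10 without replicate C of the treated cells, and 9 secretory senescence factors rose without replicate C of the untreated cells. TGFA, a ligand of the epidermal growth factor receptor, rose by 8.11 ± 0.48 (0.694 to 192 CPM), and the oxytocin receptor gene OXTR fell by -5.54 ± 0.66.

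edgeR called 5359 genes at 72 h in MYCN-high cells, 2708 higher and 2651 lower. Of the 21 genes followed throughout, 18 passed. CCND1 (1.5 ± 0.26), FAS (1.44 ± 0.27), BAX (1.25 ± 0.26) and TXNIP (2.72 ± 0.30) rose, and CCNE2 (-3.65 ± 0.53), E2F1 (-3.70 ± 0.62), LMNB1 (-4.05 ± 0.35) and NCL (-1.10 ± 0.25) fell. MYCN (0.58 ± 0.29), MYC and ABCB1 did not pass. IL6 stood at 0.465 CPM and passed edgeR's test, but not without replicate C of the untreated cells (adjusted p = 0.24) or of the treated cells (adjusted p = 0.31). Leaving out each library gave from 3619 genes, without replicate C of the untreated cells, to 4467, without replicate B of the treated cells. Replicates B and C of the treated cells differed in the mitosis list, with mean log2 CPM of 2.52 and 4.44.

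**Figure D2:**
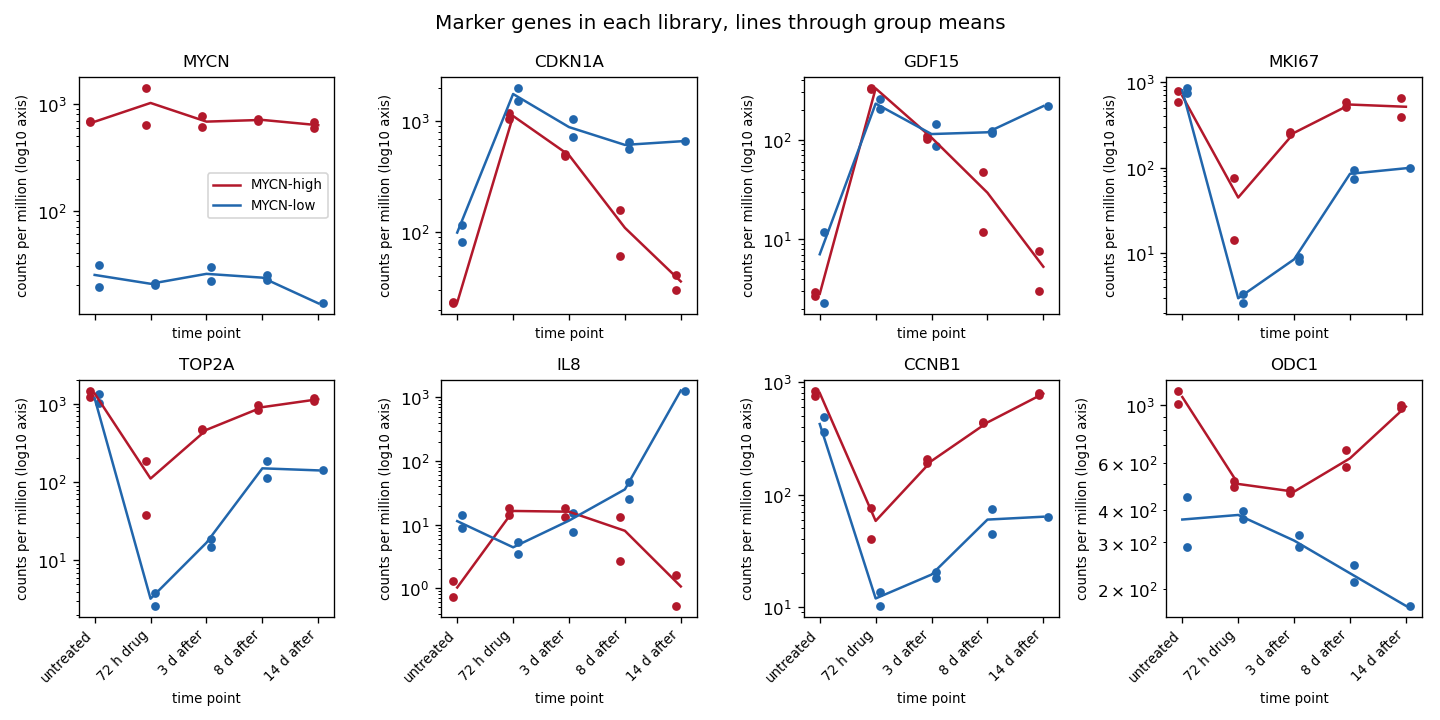
CPM on a log10 axis for MYCN, CDKN1A, GDF15, MKI67, TOP2A, IL8, CCNB1 and ODC1 in each library, by time point and MYCN state, with 1 point per library and lines through the group means. MKI67 fell to 44.6 CPM in MYCN-high cells and 2.96 CPM in MYCN-low cells at 72 h, and IL8 stood at 1280 CPM in the MYCN-low library at 14 days.

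MYCN-low cells also raised CDKN1A and GDF15 and lost cell cycle transcripts at 72 h. CDKN1A rose from 99.3 to 1760 CPM (4.15 ± 0.37), GDF15 from 7.07 to 232 CPM (5.07 ± 0.68) and MDM2 by 2.71 ± 0.30. MKI67 fell from 797 to 2.96 CPM (-8.07 ± 0.64), TOP2A from 1170 to 3.25 CPM (-8.49 ± 0.64) and CCNB1 from 424 to 11.9 CPM (-5.15 ± 0.32). The transcription factor gene E2F8 and the mitotic genes KIF18B and TROAP had no counts in either treated library, which makes them at least 213-fold, 328-fold and 467-fold lower at a floor of 3 counts over the group. CYFIP2 (4.17 ± 0.37) and C12orf5 (TIGAR), a regulator of glycolysis (2.96 ± 0.19), rose. All 44 genes of G2 and mitosis (44 adjusted over the list alone; median -6.96), 45 of 47 of DNA replication (45 adjusted over the list alone; median -3.30), 23 of 25 of homologous recombination and the Fanconi pathway (23 adjusted over the list alone; median -3.63) and 42 of 42 histone genes (42 adjusted over the list alone; median -5.49) fell. The thymidine kinase gene TK1 fell by -8.21 ± 0.60, the replication gene CDC45 by -8.62 ± 0.63 and the polymerase gene POLQ by -6.23 ± 0.50. camera's adjusted p for these 4 lists was 2.18e-114, 1.06e-67, 2.24e-37 and 4.07e-81, with 0.0118, 0.0286, 0.0262 and 0.0118 as adjusted p with an estimated correlation. Of 32 lysosome and autophagy genes 17 rose and 1 fell (21 and 1 adjusted over the list alone; 10 rose without replicate B of the treated cells), at camera's adjusted p of 3.26e-07 and adjusted p = 0.208 with an estimated correlation.

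edgeR called 3305 genes at 72 h in MYCN-low cells, 1516 higher and 1789 lower. TGFA (4.90 ± 0.41), the interferon-inducible gene TRIM22 (4.33 ± 0.44) and the ephrin receptor gene EPHA4 (4.26 ± 0.64) had large rises. In the set of 21 genes followed throughout, 14 passed, with BBC3 (3.62 ± 0.35) and TXNIP (2.17 ± 0.29) higher and CCNE2 (-6.13 ± 0.67), E2F1 (-5.66 ± 0.73) and LMNB1 (-4.48 ± 0.36) lower. BAX, FAS and IL6 passed but not in every edgeR fit without a library, with adjusted p up to 0.229 (FAS, without replicate B of the untreated cells). ABCB1, CCND1, IL8, MYC, MYCN, NCL and ODC1 did not pass. Without replicate B of the treated cells 1806 genes were called, without replicate C of them 2022, and without replicate C of the untreated cells 4755.

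The difference between these responses was tested directly at each time. At 72 h it was called for 1581 genes, 981 of which rose more or fell less in MYCN-high cells and 600 the reverse. Genes of G2 and mitosis fell less in MYCN-high cells in 36 of 44 cases (41 adjusted over the list alone), with a median difference of 2.95, and MKI67 (4.12 ± 0.71), TOP2A (4.88 ± 0.70) and KIF20A, a mitotic kinesin (5.28 ± 0.79), among them. Of 21 NF-kappaB targets 11 rose more in MYCN-high cells (13 adjusted over the list alone; median 2.67), including IL8 (5.37 ± 0.89), TNFAIP3 (3.75 ± 0.59) and RELB, an NF-kappaB subunit (3.49 ± 0.49). camera gave 7.67e-30 and 2.04e-10 for these lists, and adjusted p = 0.681 and 0.148 with an estimated correlation. Without replicate C of MYCN-high cells at 72 h 19 mitosis genes were called, with a list median of 1.58, and 20 were called without replicate C of untreated MYCN-high cells and 16 without replicate B of MYCN-low cells at 72 h, while 7 NF-kappaB targets were called without replicate C of the latter. The neuropeptide precursor gene VGF differed by 9.21 ± 1.48 and OXTR by -5.12 ± 0.81. The RNA-quality list of structured and mitochondrial ribosomal RNAs moved with these groups, with a median difference of 1.74 over 5 genes at camera's adjusted p of 0.00446, adjusted p = 0.711 with an estimated correlation, and 0.05 without replicate B of untreated MYCN-low cells, where the median was 0.98. Of the 21 genes followed throughout, CCNB1 and ODC1 also passed, but not in edgeR fits without certain libraries, with adjusted p up to 0.183 (CCNB1, without replicate C of MYCN-high cells at 72 h). CDKN1A (1.44 ± 0.47), MDM2 (-0.36 ± 0.40), GDF15, BBC3 and the remaining genes did not pass. The number of called genes moved by over 1.5 times without 7 of the 8 libraries. Without replicates B and C in turn it was 734 and 561 for untreated MYCN-high cells, 693 and 4365 for untreated MYCN-low cells, and 451 and 768 for MYCN-low cells at 72 h, and without replicate C of MYCN-high cells at 72 h it was 496, while without replicate B of those cells it was 2057.

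After removal of the drug, MYCN-high cells moved back towards the untreated state. At 3 days edgeR called 4560 genes, 2235 higher and 2325 lower, at 8 days 1269, 664 higher and 605 lower, and at 14 days 0. At 3 days CDKN1A stood at 496 CPM (4.42 ± 0.38), GDF15 at 105 CPM (5.22 ± 0.71) and CCNB1 at 199 CPM (-2.00 ± 0.28). All 44 genes of G2 and mitosis were lower than in untreated cells (44 adjusted over the list alone; median -2.00) and of 32 lysosome and autophagy genes 26 were higher (26 adjusted over the list alone). camera gave 7.52e-21 and 2.47e-16, with adjusted p = 0.23 and 0.081 with an estimated correlation. Adrenergic and neuronal genes rose in 7 of 17 cases and fell in 1 (7 and 1 adjusted over the list alone), with the granule proteins CHGB (3.79 ± 0.32) and SCG2 (2.97 ± 0.49) and the neurofilament gene NEFL (2.78 ± 0.29), and 11 of 18 YAP and TGF-beta targets fell while 2 rose (11 and 2 adjusted over the list alone; 7 fell without replicate B of the untreated cells), AJUBA by -2.05 ± 0.24 and EDN1 by -4.34 ± 0.59. camera gave 0.000831 and 0.000135, with adjusted p = 0.119 and 0.231 with an estimated correlation. The tissue plasminogen activator gene PLAT rose by 6.35 ± 1.04 and the stem cell marker LGR5 fell by -5.41 ± 0.66. The chemerin receptor gene CMKLR1 had no counts in untreated MYCN-high cells and was at least 106-fold higher at 3 days and at least 568-fold higher at 8 days, at the floor of 3 counts over the group. Of the 21 genes followed throughout, 17 passed at 3 days, with BBC3, FAS, IL8, MDM2 and TXNIP higher and LMNB1 and ODC1 lower in every edgeR fit without a library. BAX, CCND1, CCNE2, E2F1, MKI67, NCL and TOP2A passed with all libraries, and lost the call in some of those fits with adjusted p up to 0.161 (CCNE2, without replicate C at 3 days). ABCB1, IL6, MYC and MYCN did not pass.

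At 8 days, CDKN1A stood at 110 CPM (2.24 ± 0.35) and was still higher in MYCN-high cells than before treatment, as were FDXR (1.52 ± 0.26) and EDA2R, a receptor of the tumor necrosis factor family (1.73 ± 0.26). YAP and TGF-beta targets were lower in 12 of 18 cases (13 lower and 1 higher adjusted over the list alone; 7 lower without replicate B of the untreated cells or replicate C at 8 days), with AXL, a receptor tyrosine kinase (-1.49 ± 0.23), and AMOTL2 (-2.48 ± 0.27) as examples, and 7 of 17 adrenergic and neuronal genes were higher (8 higher and 1 lower adjusted over the list alone; 4 higher without replicate C of the untreated cells), with MAP2 at 2.65 ± 0.43. camera gave 1.54e-13 and 9.01e-05 for these lists, and adjusted p = 0.1 and 0.1 with an estimated correlation. HAS2, which makes hyaluronan (7.68 ± 1.13), and THSD7A (6.28 ± 0.45) rose, and DIO2, a deiodinase, fell by -5.10 ± 0.77. The RNA-quality list had a median of 0.68 at 8 days and 1.09 at 14 days, with camera's adjusted p of 0.0365 and 0.000438 and adjusted p = 0.653 and 0.486 with an estimated correlation. At 8 days camera's adjusted p for it was 0.082 without replicate C of the untreated cells and 0.186 without replicate C at 8 days, and with ERCC scaling it was 0.061 at 8 days and 0.0633 at 14 days. Without replicate C of the untreated cells its median at 14 days was 0.72. Besides CDKN1A, the genes BBC3, GDF15, IL8, TXNIP and ODC1 passed at 8 days with all libraries and lost the call in some edgeR fits without a library, with adjusted p up to 0.339 (TXNIP, without replicate B at 8 days), and the other 15 of the 21 genes did not pass. At 8 days 347 and 561 genes were called without replicates B and C of the untreated cells, and 436 and 492 without replicates B and C at 8 days. At 3 days these counts were 2948 and 2808 without the untreated replicates, and 2783 and 2933 without the replicates at 3 days.

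At 14 days no gene differed from untreated MYCN-high cells by edgeR's quasi-likelihood test, including the 21 followed throughout. The smallest adjusted p was 0.0529 and 1245 genes had an unadjusted p under 0.05. DESeq2 called 57 genes, and edgeR called 309 with no filter on low counts, 5 with the replicate letter as a block, 39 without replicate B at 14 days and 1 without replicate B of the untreated cells. CDKN1A stood at 36 CPM (0.63 ± 0.34), MKI67 at 514 CPM (-0.42 ± 0.46) and CCND1 at 112 CPM (-1.04 ± 0.25). As a set, 65 nuclear genes of the respiratory chain had a median of 0.27 and 74 cytosolic ribosomal proteins of 0.28, with none called singly among all genes, at camera's adjusted p of 6.07e-12 and 1.27e-11, with adjusted p = 0.486 and 0.62 with an estimated correlation and 0.101 and 0.135 with ERCC scaling. Without replicates B and C at 14 days in turn the ribosomal protein median was 0.47 and 0.10, and 1 gene of the respiratory chain was called without replicate B.

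**Figure D3:**
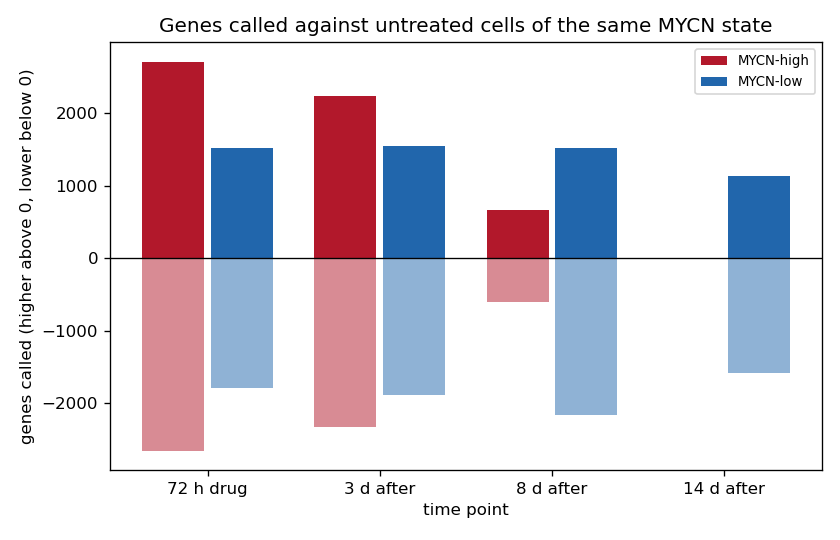
Number of genes called against untreated cells of the same MYCN state (edgeR, Benjamini-Hochberg adjusted p below 0.05), higher genes above and lower genes below 0, at 72 h and at 3, 8 and 14 days after removal of doxorubicin. MYCN-high cells went from 5359 genes at 72 h to 0 at 14 days, and MYCN-low cells from 3305 to 2716.

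MYCN-low cells still differed from untreated cells at 14 days. edgeR called 3431 genes at 3 days, 1548 higher and 1883 lower, 3681 at 8 days, 1516 higher and 2165 lower, and 2716 at 14 days, 1129 higher and 1587 lower. CDKN1A stood at 887 CPM at 3 days (3.16 ± 0.36), 613 CPM at 8 days (2.63 ± 0.35) and 661 CPM at 14 days (2.74 ± 0.39), and GDF15 at 115, 119 and 219 CPM. MKI67 was at 8.43, 84.4 and 98.1 CPM against 797 CPM before treatment, and TOP2A at 16.8, 150 and 141 CPM against 1170 CPM. All 44 genes of G2 and mitosis were lower at 3, 8 and 14 days (44 adjusted over the list alone each time), with medians of -5.84, -3.05 and -3.02, and all 42 histone genes (42 adjusted over the list alone each time), with medians of -5.36, -4.15 and -3.93. camera gave 5.8e-97, 3.06e-46 and 2.69e-33 for mitosis, with 0.0282, 0.117 and 0.0906 as adjusted p with an estimated correlation. For histones it gave 9.7e-82, 1.63e-66 and 9.57e-48, with 0.0257, 0.0444 and 0.048 as adjusted p with an estimated correlation. CYFIP2 was higher by 3.58 ± 0.36, 3.03 ± 0.36 and 3.27 ± 0.39. Genes of glycolysis and hypoxia rose, 11 of 28 at 3 days and 11 at 8 days with 1 lower each time, and 14 at 14 days (11, 12 and 15 higher and 1, 1 and 1 lower adjusted over the list alone), with the prolyl hydroxylase gene P4HA1 at 1.76 ± 0.19, 2.05 ± 0.19 and 2.59 ± 0.21 and the growth factor gene VEGFA at 1.74 ± 0.25, 1.92 ± 0.25 and 2.25 ± 0.29. camera gave 0.000598, 7.11e-06 and 2.85e-12, with adjusted p = 0.314, 0.148 and 0.048 with an estimated correlation. Of 22 genes of cholesterol synthesis 8, 16 and 10 fell (10, 18 and 11 adjusted over the list alone), with the isomerase gene EBP at -1.55 ± 0.20, -1.61 ± 0.20 and -1.85 ± 0.27, at camera's adjusted p of 0.000609, 1.52e-09 and 1.92e-07 and adjusted p = 0.385, 0.117 and 0.117 with an estimated correlation. Without replicate B of the same time 5 of these genes fell at 3 days and 9 at 8 days, and 5 fell without replicate C at 3 days, while 5 genes of glycolysis and hypoxia rose without replicate B at 3 days. ANGPTL4, a secreted lipase inhibitor, rose by 4.60 ± 0.59, 5.28 ± 0.60 and 5.90 ± 0.65, and the serotonin receptor gene HTR2A by 4.46 ± 0.63 at 3 days and 4.41 ± 0.63 at 8 days.

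The lone MYCN-low library at 14 days held high levels of inflammatory transcripts. IL8 stood at 1280 CPM against 11.4 CPM before treatment (6.81 ± 0.68), IL1B at 52.5 against 0.424 CPM (6.90 ± 0.55), the complement gene C3 at 145 against 1.75 CPM (6.40 ± 1.13) and the superoxide dismutase gene SOD2 at 1250 against 92.4 CPM (3.75 ± 0.42). IL6 was at 36.2 CPM, against 0.0674 CPM in untreated libraries. Of 21 NF-kappaB targets 10 rose (13 adjusted over the list alone; median 2.30, and 1.5 without replicate B of the untreated cells), of 38 secretory senescence factors 19 rose and 1 fell (22 and 1 adjusted over the list alone; median 2.4) and of 35 interferon response genes 12 rose (13 higher and 1 lower adjusted over the list alone; median 0.83), with IFIH1, a sensor of viral RNA, at 1.81 ± 0.30. camera gave 8.17e-12, 3.37e-12 and 2.63e-06 for these lists, with 0.048, 0.0747 and 0.048 as adjusted p with an estimated correlation. This group has no replicate, so its spread is taken from the other groups of the fit. Among the 21 genes followed throughout, 14 passed at 3 days, 16 at 8 days and 14 at 14 days. BBC3, CCND1, FAS, MDM2 and TXNIP were higher at 14 days and CCNB1, LMNB1 (-3.02 ± 0.45) and ODC1 (-1.09 ± 0.24) lower. FAS and IL6 at 3 days, and CCNE2, E2F1, FAS, IL8 and ODC1 at 8 days, passed with all libraries but lost the call in some edgeR fits without a library, with adjusted p up to 0.281 (FAS at 3 days, without replicate B of the untreated cells). ABCB1, BAX, MYC, MYCN and NCL did not pass at any of these times. Without replicate C of the untreated cells 4909, 5111 and 4207 genes were called at 3, 8 and 14 days, while 1912 and 2030 were called without replicates B and C at 3 days, and 1948 and 2185 without those at 8 days. For 14 days 2356 were called without replicate B of the untreated cells.

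**Figure D4:**
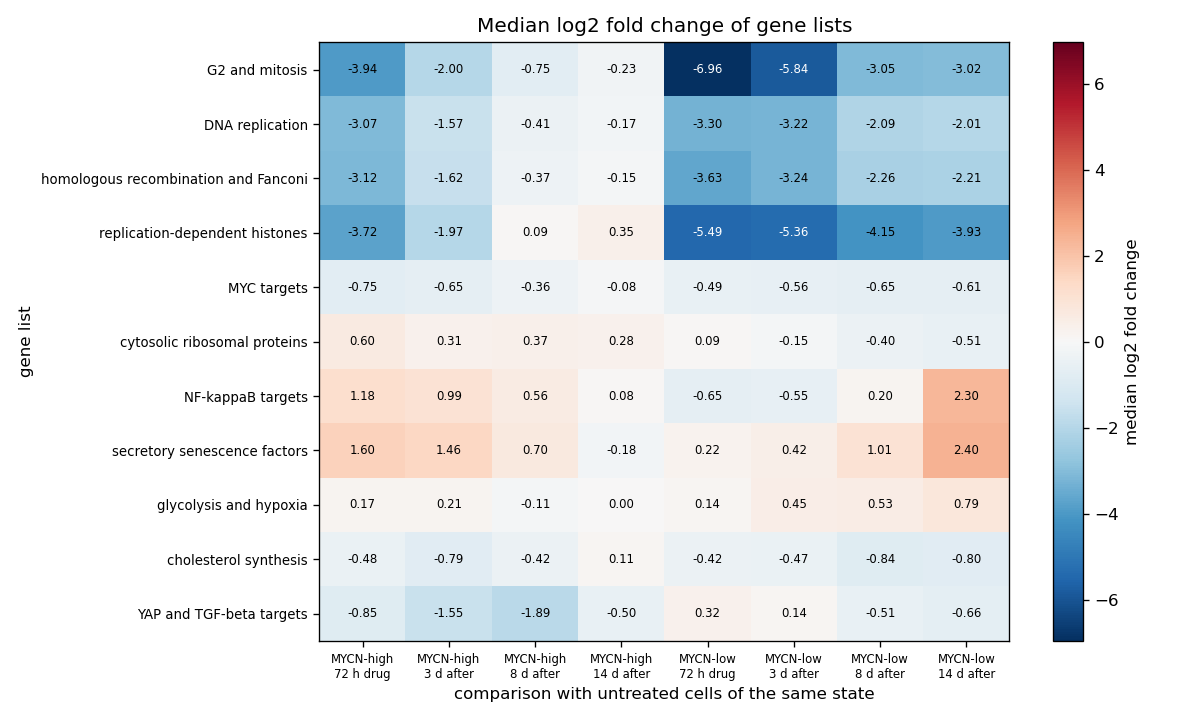
Median log2 fold change against untreated cells of the same MYCN state for 11 gene lists, in 8 comparisons, as a colour scale from blue (lower) to red (higher) with the value printed in each cell. The mitosis list went from -3.94 at 72 h to -0.23 at 14 days in MYCN-high cells and from -6.96 to -3.02 in MYCN-low cells.

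The difference between the responses was called for 1122 genes at 3 days, 939 at 8 days and 1096 at 14 days. Genes of G2 and mitosis were lower in MYCN-low cells relative to their controls throughout, with 44, 39 and 39 of 44 called (44 adjusted over the list alone each time) and medians of 3.94, 2.4 and 2.83 at 3, 8 and 14 days. Histone genes were called in 36, 42 and 42 of 42 cases (41, 42 and 42 adjusted over the list alone), with medians of 3.42, 4.09 and 4.34. camera gave 5.22e-68, 7.81e-33 and 1.35e-33 for mitosis, and adjusted p = 0.0826, 0.249 and 0.123 with an estimated correlation. At 8 days 9 and 4 mitosis genes were called without replicates B and C of untreated MYCN-high cells, 18 and 10 without replicates B and C of MYCN-high cells at 8 days and 1 without replicate B of MYCN-low cells at 8 days, and at 14 days 15 and 15 without the untreated MYCN-high replicates and 20 and 24 without those at 14 days. For histones it gave 3.77e-45, 2.31e-91 and 2.28e-66, with 0.0826, 0.0152 and 0.0429 as adjusted p with an estimated correlation. LMNB1 differed by 2.76 ± 0.45, 2.44 ± 0.44 and 2.69 ± 0.52, MKI67 by 5.13 ± 0.70 at 3 days, TOP2A by 4.58 ± 0.67 at 3 days, CCNB1 by 2.44 ± 0.39 at 3 days and 2.72 ± 0.45 at 14 days, and ABCC3, an efflux transporter, by 3.74 ± 0.40 at 3 days. At 8 days the serpin gene SERPINF1 differed by 6.17 ± 0.82 and P4HA1 by -1.94 ± 0.26. At 14 days IL8 differed by -6.71 ± 1.08, CCND1 by -3.33 ± 0.39, SOD2 by -4.06 ± 0.54 and TXNIP by -2.19 ± 0.43. At that time 6 of 21 NF-kappaB targets were lower in the MYCN-high response (11 adjusted over the list alone; median -1.0), as were 10 of 28 genes of glycolysis and hypoxia (12 adjusted over the list alone; median -0.68). camera gave 5.75e-10 and 5.04e-12, and adjusted p = 0.0804 and 0.0804 with an estimated correlation. Of the NF-kappaB targets 3 were lower without replicate B of untreated MYCN-high cells, and their median was -1.64 without replicate B of untreated MYCN-low cells and -2.06 without replicate C of MYCN-high cells at 14 days. The RNA-quality list moved with these groups, with medians of 1.47, 1.29 and 1.28 at camera's adjusted p of 0.00173, 0.00209 and 0.0455 and adjusted p = 0.408, 0.284 and 0.39 with an estimated correlation. Without replicate B of untreated MYCN-low cells its medians were 0.59, 0.67 and 0.39 and camera gave it 0.0703 at 8 days and 0.37 at 14 days, and at 14 days 0.0578 without replicate C of untreated MYCN-high cells and 0.123 without replicate C of MYCN-high cells at 14 days or with ERCC scaling. CCNE2, E2F1, IL8 and ODC1 at 3 days, CCNB1, CCND1, MDM2, MKI67 and TOP2A at 8 days, and BBC3, CDKN1A (-2.10 ± 0.52), GDF15, MDM2 and TOP2A at 14 days also passed, but each lost the call in some edgeR fits without a library, with adjusted p up to 0.204 (MDM2 at 8 days, without replicate C of MYCN-high cells at 8 days). The others of the 21 genes did not pass at these times. These counts moved with most libraries left out. Without replicates B and C of untreated MYCN-high cells they were 528 and 486 at 3 days, 248 and 373 at 8 days, and 346 and 575 at 14 days. Without replicates B and C of MYCN-high cells of the same time they were 541 and 382, 623 and 246, and 648 and 528. Without replicate C of untreated MYCN-low cells they were 3848, 3036 and 2556, and without replicate B 663, 790 and 1154. Leaving out replicates B and C of MYCN-low cells of the same time gave 441 and 604 at 3 days and 266 and 556 at 8 days, and the lone MYCN-low library at 14 days was not left out.

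Compared directly at each time, treated MYCN-high cells held more cell cycle and ribosome transcripts and fewer matrix transcripts than MYCN-low cells. edgeR called 4428 genes at 72 h, 2294 higher and 2134 lower in MYCN-high cells, 4706 at 3 days (2517 and 2189), 6492 at 8 days (3458 and 3034) and 6190 at 14 days (3159 and 3031). MYCN differed by 5.64 ± 0.36, 4.75 ± 0.34, 4.92 ± 0.34 and 5.55 ± 0.49. MYC targets were higher in 40, 42, 44 and 41 of 46 cases, with 1 lower at 3 days (41, 42, 44 and 44 higher and 1, 1, 0 and 0 lower adjusted over the list alone), at camera's adjusted p of 3.02e-24, 4.51e-22, 1.22e-26 and 6.26e-24, with 0.0457, 0.0421, 0.0263 and 0.0347 as adjusted p with an estimated correlation. Of 74 cytosolic ribosomal proteins 69, 67, 73 and 73 were higher (73, 74, 73 and 74 adjusted over the list alone), RPL14 by 1.40 ± 0.19 at 72 h, at camera's adjusted p of 6.65e-24, 1.9e-17, 1.04e-22 and 6.08e-18 and adjusted p = 0.198, 0.248, 0.139 and 0.151 with an estimated correlation. Without replicate B of the MYCN-low cells 45 of them were higher at 72 h and 35 at 3 days, and 38 at 3 days without replicate C of the MYCN-high cells. Matrix and mesenchymal genes were lower in 25, 24, 24 and 25 of 32 cases, with 1 higher at 8 and at 14 days (26, 25, 26 and 26 lower and 0, 0, 1 and 1 higher adjusted over the list alone). THBS1, a matrix glycoprotein, differed by -5.56 ± 0.49 at 72 h, -6.26 ± 0.50 at 3 days and -5.32 ± 0.48 at 8 days, and the contractile protein gene TAGLN by -8.02 ± 0.91 at 72 h. camera gave 9.57e-18, 3.85e-19, 7.55e-14 and 3.53e-12 for the matrix list, with 0.0523, 0.0421, 0.0645 and 0.0588 as adjusted p with an estimated correlation. Genes of G2 and mitosis were higher in 43 of 44 cases at 72 h and 44 at 3, 8 and 14 days (43, 44, 44 and 44 adjusted over the list alone), at camera's adjusted p of 4.19e-27, 1.67e-47, 3.81e-19 and 6.08e-18 and adjusted p = 0.194, 0.0866, 0.166 and 0.151 with an estimated correlation. The RNA-quality list moved with these groups at 72 h, with a median of 0.80 at camera's adjusted p of 0.0428 and adjusted p = 0.465 with an estimated correlation, and had medians of 0.96, 0.70 and 0.41 at 3, 8 and 14 days that did not pass. At 72 h camera's adjusted p for it was 0.0558 and 0.0702 without replicates B and C of the MYCN-high cells, 0.159 without replicate B of the MYCN-low cells, 0.0568 with the replicate block and 0.0585 with ERCC scaling, and its median was 0.52 and 1.81 without replicates B and C of the MYCN-low cells. At 14 days 29 of 38 secretory senescence factors were lower in MYCN-high cells (30 adjusted over the list alone; median -4.00, and -3.90 with members at 0 counts set to their bound), at camera's adjusted p of 1.32e-14 and adjusted p = 0.0444 with an estimated correlation. Of 6 tested immune markers 3 were lower there too, PTPRC, LYZ and CD68, which are named after their values were seen (list median -4.12, and -2.46 with members at 0 counts set to their bound; camera's adjusted p = 0.0635). IL8 differed by -10.19 ± 0.81 and the protease gene PAPPA by -9.58 ± 1.65. IL1B had no counts in MYCN-high libraries at 14 days and was at least 647-fold lower there, at the same floor.

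Of the 21 genes followed throughout, 12, 13, 20 and 19 passed between the treated states at 72 h and at 3, 8 and 14 days. CCNB1, CCNE2, MKI67, MYCN and TOP2A were higher in MYCN-high cells each time, LMNB1 at 3, 8 and 14 days, E2F1 at 3 days, NCL and ODC1 at 8 and 14 days, and ABCB1 at 14 days, while MYC and TXNIP were lower each time. CCND1 was higher at 72 h and lower at 8 and 14 days, and CDKN1A, FAS, IL6 and IL8 were lower at 8 and 14 days, as were BBC3, GDF15 and MDM2 at 14 days. Some calls ended in edgeR fits without a library, namely ABCB1, IL8, LMNB1 and NCL at 72 h, ABCB1, IL6, NCL and ODC1 at 3 days, and ABCB1, BBC3, E2F1, GDF15 and MDM2 at 8 days, with adjusted p up to 0.31 (LMNB1 at 72 h, without replicate C of the MYCN-high cells). BAX did not pass at any of these times. At 72 h 2683 genes were called without replicate B of the MYCN-low cells and 2703 without replicate C of the MYCN-high cells, and at 3 days 3082 and 2929 without the replicates of those letters.

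Between 72 h and 14 days, 5260 genes were called in MYCN-high cells and 465 in MYCN-low cells, 312 higher and 153 lower. The MYCN-low group at 14 days has 1 library, and with 1 library left at 14 days 3719 and 3720 genes were called in MYCN-high cells, without replicates B and C in turn. The difference between these changes of the states was not tested. In MYCN-high cells CDKN1A fell by -4.96 ± 0.39 and GDF15 by -5.94 ± 0.71, and all 44 genes of G2 and mitosis rose (44 adjusted over the list alone; median 3.71), CCNB1 by 3.76 ± 0.30 and MKI67 by 3.53 ± 0.51. camera gave 3.48e-46 for the mitosis list, with 0.0491 as adjusted p with an estimated correlation. In MYCN-low cells 14 of 21 NF-kappaB targets rose (18 adjusted over the list alone; median 2.44; 8 rose without replicate B or C at 72 h), IL8 by 8.18 ± 0.73 and the chemokine CXCL1 by 6.36 ± 0.91, and 40 of 44 genes of G2 and mitosis rose (44 adjusted over the list alone; median 3.84), TOP2A by 5.44 ± 0.60 and MKI67 by 5.05 ± 0.61. camera gave 1.61e-33 and 3.5e-115, with 0.00305 and 0.018 as adjusted p with an estimated correlation. Of the 21 genes followed throughout, 17 passed in MYCN-high cells, with CCNE2, E2F1, LMNB1, ODC1 and TOP2A higher and BBC3, CCND1, IL8, MDM2 and TXNIP lower, while the calls of BAX, FAS and NCL ended in some edgeR fits without a library, with adjusted p up to 0.221 (BAX, without replicate C at 72 h). In MYCN-low cells 9 passed, with CCNB1, CCND1, CCNE2 and IL6 higher, while the calls of E2F1 and ODC1 ended in some fits, with edgeR adjusted p up to 0.17 (E2F1, without replicate B at 72 h). Without replicate B at 72 h 159 genes were called in MYCN-low cells and without replicate C 231.

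The responses of the 2 states were also compared across genes, which are not independent replicates. The log2 fold changes against untreated cells had Pearson correlations of 0.485 at 72 h, 0.434 at 3 days, 0.365 at 8 days and 0.104 at 14 days over 14793 genes. At 72 h 824 genes rose in both states, against 278 for independent lists of the same sizes, and 1086 fell in both, against 321. At 3 days 791 rose in both against 234 and 1077 fell in both against 296, and at 8 days 316 against 68 and 246 against 88.5. Genes called in opposite directions numbered 106, 45 and 21 at 72 h, 3 and 8 days.

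The spike-in RNAs of the ERCC mix took 0.0116 to 0.537% of the counts of a library. Within groups this share varied by 1.08 to 16.5-fold, the most in MYCN-high cells at 72 h, with 0.0116% in replicate B and 0.191% in replicate C. A scaling on ERCC counts gave a median log2 fold change over all genes of 2.37 at 72 h, 1.62 at 3 days, 1.14 at 8 days and -1.07 at 14 days in MYCN-high cells, and of 0.52, 0.50, 1.00 and 0.38 in MYCN-low cells. For MYCN-high against MYCN-low cells these medians were 0.62 untreated and 2.51, 1.82, 0.79 and -0.83 at the later times. All changes given above are relative to the typical gene of a library, as TMM scaling sets it, and a direction on the scale of total RNA per spike-in is not given for any of them.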

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

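The tests for MYCN-high cells in an untreated library, for immune cells, for a few genes taking the counts, and for untreated cells in a treated library were chosen only after the result was seen. The results listed first are differences between the responses of MYCN-high and MYCN-low cells to doxorubicin, each past the edgeR test of the difference itself, or camera's for gene lists. These responses include any effect of time in culture. The patterns in the lone MYCN-low library at 14 days and between the untreated MYCN-low libraries, given last, are not such differences.

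At 72 h 1581 genes differed. The neuropeptide precursor VGF (9.21), the chemokine IL8 (5.37), the NF-kappaB regulators TNFAIP3 (3.75) and RELB (3.49), and the mitotic genes KIF20A (5.28), TOP2A (4.88), MKI67 (4.12) and CCNB1 (1.37) had a higher log2 response in MYCN-high cells, and OXTR (-5.12) and ODC1 (-1.15) a lower one. The list medians were 2.95 for mitosis, 2.67 for NF-kappaB targets and 1.74 for the RNA-quality list, and all of these list calls were lost with an estimated correlation. At 3 days 1122 genes differed, with MKI67 (5.13), TOP2A (4.58), CCNB1 (2.44), CCNE2 (2.53), E2F1 (2.98), LMNB1 (2.76), IL8 (3.94) and the transporter ABCC3 (3.74) higher and ODC1 (-0.93) lower, and list medians of 3.94 for mitosis, 3.42 for histones and 1.47 for the RNA-quality list. The list calls at 3 days were likewise lost with an estimated correlation.

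At 8 days 939 genes differed, with CCNB1 (1.95), LMNB1 (2.44), MKI67 (2.91), TOP2A (2.39) and SERPINF1 (6.17) higher and CCND1 (-1.57), MDM2 (-1.40) and P4HA1 (-1.94) lower, and list medians of 2.4 for mitosis, 4.09 for histones and 1.29 for the RNA-quality list. Of these lists only the histones kept the call with an estimated correlation. At 14 days 1096 genes differed, with CCNB1 (2.72), LMNB1 (2.69), TOP2A (2.81) and SERPINF1 (5.77) higher and BBC3 (-2.08), CCND1 (-3.33), CDKN1A (-2.10), GDF15 (-4.07), IL8 (-6.71), MDM2 (-1.89), P4HA1 (-2.39), SOD2 (-4.06) and TXNIP (-2.19) lower. The list medians at 14 days were 2.83 for mitosis, 4.34 for histones, -1.0 for NF-kappaB targets, -0.68 for glycolysis and hypoxia, and 1.28 for the RNA-quality list. Again only the histones kept the call with an estimated correlation.

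Genes of G2 and mitosis fell less at 72 h in MYCN-high than in MYCN-low cells, and the replicates of MYCN-high cells differed in this list. Of 36 mitosis genes called in the difference, 19 (52.8%, standard error 8.32) were still called without replicate C of these cells and 36 without replicate B, against 20 without replicate C of untreated MYCN-high cells and 16 without replicate B of MYCN-low cells at 72 h, and without replicate C of MYCN-high cells at 72 h the median difference of the 36 genes went from 3.42 to 1.96 with all 36 above 0. Whether this library carries the difference cannot be told apart from a difference between the states, because the group has 2 libraries. The share lies near the bound set in advance. Its standard error treats the 36 genes as independent, which they are not, so it does not measure the uncertainty of leaving out a library. Untreated MYCN-high cells mixed into replicate C could raise its mitosis genes, which kept 10.5% of the untreated level in C, 2.58% in B and 0.8% in MYCN-low cells. The 10 abundant genes with the lowest share kept 7.05% in median, but KIF14, NEK2, ARHGAP11A, PBK, SPC25 and SKA3 among them are mitotic too and NPR3 (1.02%), DIO2 (4.55%), LGR5 (4.57%) and KIT (7.71%) were picked as the lowest of this library, so that value decides nothing, and a small admixture cannot be told apart from slower arrest of MYCN-high cells, which was not tested.

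Inflammatory genes stood high in the lone MYCN-low library at 14 days. Immune cells in the culture are argued against by a median of 0.458 CPM for 5 immune markers, PTPRC (2.04 CPM), LYZ (0.713 CPM), CSF1R (0.306 CPM), ITGAM (0.204 CPM) and CORO1A (0.458 CPM), while CD68, which other cells express too, was at 64 CPM, although 3 of 6 immune markers were higher there than in MYCN-high cells. The 10 highest genes took 5.09% of the counts, inside the 4.41 to 6.39% of the other libraries. Removing the trend on GC content left the median difference of 21 NF-kappaB targets to 8 days at 1.42, against 1.38 before. A late inflammatory program in MYCN-low cells may be the source, as a hypothesis from the only library of its group, which further libraries of this group would test by the levels of IL8 and the NF-kappaB list.

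The untreated MYCN-low libraries differed more than the replicates of any other group. Replicate B lay at -80.1 on principal component 3, while all other libraries lay between -40.3 and 25.3. Its log2 CPM correlated less than that of C with every library outside the pair. Replicate C correlated with replicate B of untreated MYCN-high cells at Pearson r 0.967, and with its own partner at 0.966. MYCN-high cells in replicate C are argued against by MYCN itself, at 19.1 CPM in C and 30.7 CPM in B, where the genes that differ between the states would need a median of 21% of such cells. After thinning C to the total of B, 2737 genes were over 2-fold apart, against 2647 before and at most 1664 in another group. CPM already allows for the total and thinning adds sampling noise, so this number could hardly fall and decides nothing on total count. The difference rose with GC content (Pearson r 0.477 across genes, which are not independent replicates, 22.8% of the variance), and removing that trend lowered its root mean square from 0.826 to 0.726, above the 0.639 of the next group, so GC content could explain part of it and not the whole. Removing the trend on transcript length left 0.823, against at most 0.673 elsewhere, and no biological explanation was tested.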

How the results depend on the processing

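No alternative here was chosen after the result was seen. Size factors of DESeq2 in edgeR kept all 19 counts of called genes within 1.5 times, and all 84 list calls and the 4 response correlations in the text. The split into higher and lower genes moved in some contrasts. In MYCN-low cells against untreated it was 1753 and 1950 at 8 days, against 1516 and 2165 with TMM. At 14 days it was 1329 and 1363, against 1129 and 1587. The replicate block kept 18 of 19 counts and 83 of 84 list calls, and gave 5 genes at 14 days in MYCN-high cells. Deviations of same-letter replicates correlated across genes between 36 pairs of groups from -0.208 to 0.315, with a median of 0.108, 22 pairs over 0.1 and 1 under -0.1.

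The DESeq2 Wald test kept 14 counts. Against untreated MYCN-high cells it called 1968 genes at 8 days and 57 at 14 days, for the difference between responses 1726 at 3 days and 1544 at 8 days, and 800 for 14 days against 72 h in MYCN-low cells. With no count filter 12 counts were kept. The others were 2080 at 8 days and 309 at 14 days in MYCN-high cells, 2627, 2079, 1931 and 1973 for the difference between responses at 72 h, 3, 8 and 14 days, and 1095 for 14 days against 72 h in MYCN-low cells. The cause was not tested.

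ERCC scaling left 2 of 19 counts within 1.5 times, 0 genes at 14 days in MYCN-high cells and 5631 for 14 days against 72 h in these cells. Of the latter 8 were higher and 5623 lower, against 2559 and 2701 with TMM, and 2705 were called under both scalings. For MYCN-high against MYCN-low cells it gave 0 untreated, 5 at 72 h and 4 at 3 days, all higher, 0 at 8 days and 31 at 14 days, all lower. Against untreated cells it gave 70, 23 and 4 in MYCN-high cells at 72 h, 3 and 8 days, all higher. In MYCN-low cells it gave 60 at 72 h, 2 higher and 58 lower, and 0, 0 and 0 at 3, 8 and 14 days. It gave 0 for the difference between responses at each of the 4 times and 0 for 14 days against 72 h in MYCN-low cells. ERCC shares differed by up to 16.5-fold within a group, and this spread enters every gene under that scaling. Of 84 list calls 77 were kept. camera compares a list with the other genes, and this scaling shifts all genes of a library alike, so kept list calls say little. Of 510 gene values named 339 were called with TMM, of which 29 kept the call and 310 lost it, and 2 of the other 171 were called. These calls are those of the ERCC-scaled test itself. The direction was taken relative to the shift of the median gene and was kept in those 29. Subtracting that shift brings values close to the TMM scale, so a kept direction says little. Without allowing for that shift 79 changed sign, 15 of them called.

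With an estimated correlation 28 of 84 list calls were kept and 56 were not. The direction of a list does not depend on this setting.

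Leaving out each library gave 84 counts, 32 of them within 1.5 times, with the lone remaining library of a group assumed to vary like the others. Fewer libraries lower the number of calls, and counts also rose without replicate C of untreated MYCN-low cells. The lowest and highest for MYCN-high against MYCN-low cells were 2903 and 6434 untreated, 2683 and 3839 at 72 h, 2929 and 3508 at 3 days, 4490 and 5379 at 8 days and 4814 and 5092 at 14 days. In MYCN-high cells against untreated they were 3619 and 4467 at 72 h, 2783 and 2948 at 3 days, 347 and 561 at 8 days and 0 and 39 at 14 days. In MYCN-low cells they were 1806 and 4755, 1912 and 4909, 1948 and 5111, and 2356 and 4207. For the difference between responses they were 451 and 4365, 382 and 3848, 246 and 3036, and 346 and 2556. For 14 days against 72 h they were 3719 and 4303 in MYCN-high and 159 and 231 in MYCN-low cells. The MYCN-low library at 14 days could not be left out, as no library would remain. Of 354 list values 344 kept the call and 10 lost it, all of the RNA-quality list. Of 2222 gene values 174 lost the call, 33 gained it and none changed direction while called.

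Over genes called in either state the response correlations were 0.623, 0.552, 0.468 and 0.231 at 72 h, 3, 8 and 14 days. These are higher than over all genes, and the reason was not tested. In the simulations 2-fold changes were recovered at 10 to 52%, so genes that did change can be missing from counts of called genes. Those simulations changed 100 genes at each fold, far fewer than most contrasts called. The p needed for a call depends on that number, so these shares do not measure recovery in the real contrasts.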

Other observations

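No test in this part was chosen after the result was seen. Some gene groups outside the main account also differed. Before treatment, 10 of 16 heat shock genes were higher and 1 lower in MYCN-high cells (10 and 2 adjusted over the list alone; median 1.12), including the mitochondrial chaperones HSPD1 (2.07 ± 0.22) and HSPE1 (1.56 ± 0.25), at camera's adjusted p of 6.22e-05 and adjusted p = 0.109 with an estimated correlation. After 72 h in doxorubicin, 11 of 20 chaperones of the endoplasmic reticulum rose in MYCN-high cells (11 adjusted over the list alone; median 0.61; 7 rose without replicate C of the untreated cells and 6 without replicate B of the treated cells), such as the disulfide isomerase PDIA4 (0.99 ± 0.15) and EDEM1, which clears misfolded proteins (1.16 ± 0.19), at camera's adjusted p of 0.00238, with adjusted p = 0.381 with an estimated correlation and 0.0697 with ERCC scaling. In the same cells 19 of 25 genes of nucleotide and one-carbon synthesis fell (19 lower and 1 higher adjusted over the list alone; median -0.96), among them GMPS, an enzyme of guanine nucleotide synthesis (-1.66 ± 0.16), at camera's adjusted p of 8.89e-08 and adjusted p = 0.102 with an estimated correlation.

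Over 19 contrasts, camera called the ATF4 and integrated stress response list lower in 5 and the immediate early genes lower in 3, apoptosis regulators higher in 1 and anthracycline transport and reduction genes higher in 3, with 0 of these calls kept with an estimated correlation. NRF2 targets were never called, with a smallest adjusted p by camera of 0.0707 for 14 days against 72 h in MYCN-low cells. Markers of other cell types were not called either. The smallest camera adjusted p was 0.0635 for 6 tested immune markers (median -4.12, and -2.46 with members at 0 counts set to their bound, 3 lower) and 0.195 for 9 endothelial markers, both for MYCN-high against MYCN-low cells at 14 days, 0.077 for 9 epithelial markers in the difference between responses at 3 days, and 0.148 for 6 markers of Schwann cells and glia between the states at 72 h.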
